A study of Homo sapiens with 8 samples.

How the data were processed

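The series holds 8 RNA sequencing libraries from tonsillar naive B cells of 2 donors, sorted with magnetic beads. Per the labels, cells were washed for 30 min on ice in 50 mM lactose, then cultured for 16 h with buffer, 1 µg/ml recombinant human Gal-9, 50 mM lactose, or both, and dead cells were removed afterwards. Libraries were made from 100 ng RNA with an mRNA kit and sequenced as single 75 bp reads. Per the labels, reads were aligned to hg19 and counted per gene with STAR 2.5.1b, and the authors used DESeq2 1.10.1 and Cufflinks 2.2.1. The gene annotation and the strand setting are not given in the sources used here. The deposited first table holds integer counts per gene, and the deposited second table is named for TPM, although the labels speak of FPKM. Each of its columns sums to 1000000, which TPM does by construction and FPKM need not. For 99.81% of the 11638 genes counted in every library, the ratio of TPM to count, scaled per library, was constant within 1% across libraries, as for counts divided by a fixed length.

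There were 25435 rows of counts and 24791 of TPM. In 28 rows a spreadsheet had turned the symbol into a date, and 4 of these share a name with another row. For the privacy of the donors, 108 rows of XIST and Y-linked genes were left out. Total counts ranged from 1875765 to 7782841, with a median of 4726777 and a ratio of 4.15 between the deepest and the shallowest library. The 50 most abundant genes took 11.9 to 13.8% of the counts. Replicates differed by more than counting error, with a chi-square per degree of freedom of 6.33 to 9.39 in the 4 groups. Coordinates are on GRCh37, and genes whose symbol has been replaced since, such as GSG2, have none here.

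Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 11581. Counts were scaled with TMM (factors 0.988 to 1.019) and fitted with edgeR 4.0.16 under R 4.3.3, as a robust quasi-likelihood model with a mean per group over all 8 libraries. That fit leaves 4 residual degrees of freedom. The 5 comparisons were Gal-9 against buffer, Gal-9 with lactose against lactose, lactose against buffer, Gal-9 with lactose against Gal-9, and the difference of the Gal-9 responses without and with lactose. P-values were adjusted within a comparison by the Benjamini-Hochberg method with a threshold of 0.05. SEs of log2 fold changes come from the same fit, with a median of 0.226 to 0.238 in the 4 group comparisons and 0.328 for the difference of responses. Log2 CPM carried a prior count of 2. The labels pair the samples by donor, so a fit with the donor as a term (the replicate block, 3 residual degrees of freedom) was also made. Its values are given beside gene counts and called lists where it changed a call or moved a count by more than 1.5 times. For lists that were not called they are given only in part. For gene counts with 1 library left out they are given as ranges in a closing section only. The other values with 1 library left out come from fits without a donor term. Deviations from the group means correlated between libraries of a donor with r of 0.305 to 0.491 over 6 pairs. The common biological coefficient of variation was 0.171 without the block and 0.107 with it.

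Of 40 fixed gene lists, 35 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. Genes were named by rule: 12 in each direction with the largest absolute log2 fold change for Gal-9 against buffer, and 6 in each direction for the other comparisons, among genes past the threshold with a mean log2 CPM of at least 3 and the same sign in both donors. Places left went to genes past the threshold with the replicate block only, and then to the smallest p in that fit. From each list up to 4 members were named, those past the threshold in either fit with the largest absolute change, or else those with the smallest p. XIST, Y-linked genes, immunoglobulin and T cell receptor segments and classical HLA genes were never named. Of the genes the rules named, 4 are not reported here. Comparisons, tests, lists and naming rules were chosen before the data were examined.

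The fits were tested on counts simulated for all 8 libraries, from a mean per donor and the spread estimated with the replicate block. Changes were put into the Gal-9 libraries only, and Gal-9 was compared with buffer. Without the block edgeR recovered 3.0% of 67 genes changed 1.5-fold, 41.8% of 67 changed 2-fold and 68.2% of 66 changed 4-fold, with 0% of 11354 unchanged genes called. With the block it recovered 28.4%, 79.1% and 89.4%, with 0.088% of unchanged genes called. A lysosome list shifted by 1.5-fold had a camera adjusted p of 1.65e-25 with 0 of 34 other lists called, and an adjusted p of 0.103 with an estimated correlation. Simulated genes were drawn independently, so these values cannot test the preset correlation on lists whose genes vary together. In the real libraries the estimated correlation was 0.045 for the lysosome list, 0.442 for ribosomal proteins and 0.713 for the integrated stress response.

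Alternatives tried were the replicate block, RLE size factors, both together, DESeq2 1.42.0 without and with the block, no filter, a stricter filter, limma on log2 TPM with a pseudocount of 1 or 0.1 (TPM of at least 1 in 2 libraries) and without a filter, leaving out 5 immunoglobulin genes, only the 2 groups compared, and each library left out. For lists they were an estimated correlation, the block, fry, RLE, no filter and each library left out. A fit with length and GC trends removed and the block, and camera with an estimated correlation and the block, were added later. RLE in place of TMM moved the median log2 fold change over all genes by at most 0.013.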

Results

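The series measured messenger RNA in naive B cells sorted from human tonsil after 16 h in culture. Cells of 2 donors were each split over 4 groups, which gave 8 libraries and n = 2 per group. The groups were buffer, recombinant galectin-9 (Gal-9, a protein that binds galactose-containing sugars on cell surfaces) at 1 µg/ml, 50 mM lactose (a sugar that competes for the Gal-9 binding site), and Gal-9 with lactose. Replicate numbers stand for the donors, so each donor has 1 library in every group. Total counts in replicates 1 and 2 were 7782841 and 5209067 for buffer, 2487191 and 5878657 for Gal-9, 6693088 and 3741763 for lactose, and 4244487 and 1875765 for Gal-9 with lactose. At those depths 1 CPM (a count scaled by library size) stood for 1.88 to 7.78 counts. Of the genes in the count table, 11581 were tested. Levels are CPM, given as mean ± SD over both libraries of a group, and log2 fold changes are given ± SE. Adjusted p-values for genes come from edgeR's quasi-likelihood test, and those for gene lists from limma's camera test, both with Benjamini-Hochberg adjustment.

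Gal-9 was compared with buffer to ask what the lectin did to naive B cells. FOS, which encodes a transcription factor induced within minutes of stimulation, rose from 125 ± 12.8 CPM in buffer to 668 ± 77.4 CPM with Gal-9, a log2 fold change of 2.41 ± 0.29 (edgeR adjusted p = 0.00887). CCL22, which encodes a chemokine for CCR4-bearing cells, rose from 89.8 ± 14.7 to 527 ± 176 CPM (2.55 ± 0.28, edgeR adjusted p = 0.00688). SLAMF7, a surface receptor of activated B cells and plasma cells, rose from 62.3 ± 3.53 to 441 ± 71.7 CPM (2.82 ± 0.32, edgeR adjusted p = 0.00798). PAX5, the transcription factor that maintains B cell identity, fell from 222 ± 20.6 to 107 ± 23.7 CPM (-1.04 ± 0.16, edgeR adjusted p = 0.00939). RPLP1, which encodes a protein of the ribosomal stalk, fell from 1614 ± 57.9 to 817 ± 89.5 CPM (-0.98 ± 0.12, edgeR adjusted p = 0.00447). Without buffer replicate 1 the adjusted p was 0.0910 for FOS, 0.0712 for CCL22, 0.0897 for SLAMF7, 0.0632 for PAX5 and 0.0630 for RPLP1. Without Gal-9 replicate 1 and without buffer replicate 2 it was 0.101 and 0.0577 for FOS, 0.0764 and 0.0645 for SLAMF7, and 0.0577 and 0.0701 for PAX5. In GRCh37, CCL22 lies on chromosome 16 from 57392695 to 57400101 and SLAMF7 on chromosome 1 from 160708847 to 160724611. FOS lies on chromosome 14 from 75745529 to 75748933, PAX5 on chromosome 9 from 36833266 to 37034265, and RPLP1 on chromosome 15 from 69745153 to 69748544.

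Across the transcriptome, 229 genes rose and 211 fell with Gal-9, and 820 rose and 783 fell when the donor was a block in the fit. All 440 genes called without the block changed the same way in both donors, and 152 of them changed by at least 2-fold. Among genes with a mean log2 CPM of at least 3 over all libraries, those with the largest rises beside CCL22 and SLAMF7 were ZNF777 (log2 fold change 3.68 ± 0.45), TADA2B (3.25 ± 0.31), BRD1 (3.06 ± 0.39), PLXNA1 (2.85 ± 0.32), RNF19B (2.68 ± 0.33), SPHK1 (2.65 ± 0.42), ZNRF2 (2.62 ± 0.50), INPP5A (2.52 ± 0.49), BTBD2 (2.52 ± 0.36) and NFIL3 (2.43 ± 0.37). TADA2B encodes an adaptor of histone acetyltransferase complexes, BRD1 a bromodomain protein and PLXNA1 a semaphorin receptor. RNF19B encodes a ubiquitin ligase, SPHK1 a sphingosine kinase and NFIL3 a leucine zipper transcription factor. TADA2B went from 8.15 ± 0.65 to 78.5 ± 26.0 CPM and ZNF777 from 3.78 ± 0.37 to 48.5 ± 6.28 CPM. The genes with the largest falls included SDK2 (-2.18 ± 0.36), ABAT (-1.87 ± 0.32), PLXND1 (-1.76 ± 0.39), MGAT5B (-1.75 ± 0.26), RGP1 (-1.61 ± 0.29), CDKN1B (-1.48 ± 0.30), LIMK1 (-1.48 ± 0.22), CRIM1 (-1.43 ± 0.26), BCORL1 (-1.41 ± 0.30) and JRK (-1.36 ± 0.22). CDKN1B, which encodes an inhibitor of cell cycle entry, went from 35.3 ± 7.81 to 12.3 ± 2.95 CPM, and MGAT5B encodes a glycosyltransferase. The count of changed genes was 6 without buffer replicate 1, 44 without Gal-9 replicate 1, 56 without buffer replicate 2 and 893 without Gal-9 replicate 2. Of these 24 genes with the largest changes at that level, only TADA2B and BRD1 stayed past the threshold without buffer replicate 1, while 9 did so without Gal-9 replicate 1 and 10 without buffer replicate 2. These fits with 1 library left out had no donor term, so 1 group held 1 donor while the others held both. Differences between the donors therefore enter them, and part of the loss of calls may come from the ignored pairing. Across the 6236 genes with a mean log2 CPM of at least 5, the Gal-9 change in one donor correlated with that in the other (r = 0.728, across genes, which are not independent replicates).

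Ribosomal protein transcripts were the list that moved most evenly. Of 46 genes for cytosolic ribosomal proteins, 31 fell with Gal-9 and 0 rose, 43 fell with the replicate block, and 44 fell when adjusted over the list alone. Their median log2 fold change was -0.67 (camera adjusted p = 4.513e-23, adjusted p = 0.375 with an estimated correlation). RPL37 fell by 1.01 and RPL27 by 0.94 on the log2 scale. Genes of the respiratory chain and ATP synthase had a median of -0.29 (33 genes, camera adjusted p = 0.000387, adjusted p = 0.608 with an estimated correlation), although 0 passed the threshold one by one and 7 fell and 1 rose with the replicate block. Lysosome and autophagy genes moved the other way: of 27 tested, 10 rose and 0 fell, 18 rose and 1 fell with the replicate block, and 15 rose when adjusted over the list alone. Their median was 0.64 (camera adjusted p = 1.748e-06, adjusted p = 0.375 with an estimated correlation). MCOLN1, which encodes a lysosomal calcium channel, rose from 11.8 ± 0.32 to 37.1 ± 6.21 CPM (1.65 ± 0.25, edgeR adjusted p = 0.00887). GLA (1.12 ± 0.20), a lysosomal galactosidase, and CTSA (1.06 ± 0.19), a lysosomal carboxypeptidase, also rose. The calls for these 3 lists were kept with each library left out in turn.

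With Gal-9, camera called the immediate early, activation marker, NF-kappaB target, cytokine and memory gene lists as higher, with a minority of the genes of each past the threshold. Of 22 immediate early genes, 4 rose (7 rose and 1 fell with the replicate block, 5 rose and 1 fell adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00414, adjusted p = 0.632 with an estimated correlation). NR4A2, an orphan nuclear receptor gene, rose by 1.78 ± 0.21 and FOSB by 1.34 ± 0.27 on the log2 scale. Of 18 B cell activation markers, 3 rose (9 with the replicate block, 6 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 0.00121, adjusted p = 0.375 with an estimated correlation). Of 24 NF-kappaB targets, 2 rose (11 rose and 1 fell with the replicate block, 7 rose and 1 fell adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00837, adjusted p = 0.632 with an estimated correlation). ICAM1, an adhesion molecule on both lists, rose by 1.45 ± 0.28 on the log2 scale (edgeR adjusted p = 0.0225). FCER2 (1.40 ± 0.44) and CD69 (0.91 ± 0.27) rose in the replicate block fit only. Of 23 cytokine and chemokine genes, 2 rose (10 rose and 2 fell with the replicate block, 5 rose adjusted over the list alone), with a median of 0.91 (camera adjusted p = 0.0233, adjusted p = 0.375 with an estimated correlation). That median was the same with IL1B, at 0 in both buffer libraries, set to the bound from a floor of 3 counts per group. Of 12 memory B cell genes 1 rose (2 with the replicate block, 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.0233, adjusted p = 0.375 with an estimated correlation). That gene was FCRL4, an immunoglobulin receptor-like gene, which went from 0.84 ± 0.65 to 20.7 ± 2.47 CPM (4.48 ± 0.55). Without Gal-9 replicate 2 the camera adjusted p was 0.138 for immediate early genes, 0.0907 for NF-kappaB targets, 0.0626 for activation markers, 0.176 for cytokines and 0.120 for memory genes. Without buffer replicate 1 it was 0.323, 0.417, 0.0645 and 0.129 for the first 4 of these lists.

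Among the cytokine genes, IL1B, IL32, CXCL8 and CCL5 were past the threshold only with the replicate block, and their log2 differences lay at 0, 0, -1.66 and 0.86 in replicate 1 and at 3.29, 3.25, 2.76 and 2.40 in replicate 2. With the prior count, a difference of 0 arises where a gene has no count in either library. For IL1B, at 0 in both buffer libraries, it stands for a lack of detection rather than a measured lack of change. Transcripts of other cell types were also higher in Gal-9 replicate 2. Summed CPM of 24 monocyte, macrophage and dendritic cell markers were 62.7 in buffer and 297 with Gal-9 in replicate 2, and 59.9 and 59.0 in replicate 1. S100A9, FCER1G and CST3 were at 0 CPM in both of these replicate 1 libraries, so the sums there came from other list members. For 19 T cell markers the sums were 41.0 and 117 in replicate 2, and 50.7 and 54.2 in replicate 1. Summed NK cell markers went from 10.2 to 48.5 CPM in replicate 2 and from 0.91 to 1.22 CPM in replicate 1. Plasmacytoid dendritic cell markers were higher with Gal-9 in both replicates, at 44.1 and 94.1 CPM in buffer and Gal-9 of replicate 1 and at 51.9 and 75.5 CPM in replicate 2. Of these lists, T cell markers were called in the replicate block fit only (camera adjusted p = 0.0253, 0.696 with an estimated correlation and the block, 0.398 without the block), and monocyte, macrophage and dendritic cell markers in neither fit (0.0883 with the block, 0.187 without). NK cell markers had too few tested genes for camera, as did plasmacytoid dendritic, follicular dendritic and stromal, epithelial, and erythroid, platelet and granulocyte markers. Of all these other-cell lists 0 genes were past the threshold without the block. With it 3 of 10 monocyte, macrophage and dendritic cell markers, 1 of 11 T cell markers, 1 NK cell and 2 plasmacytoid dendritic cell markers rose and 1 epithelial marker fell.

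Camera also called the heat shock, integrated stress response, cholesterol biosynthesis and MYC lists as higher with Gal-9. It did not call osmotic stress (adjusted p = 0.727), endoplasmic reticulum chaperones (0.154) or glycolysis and hypoxia (0.968). Of 18 heat shock genes, 3 rose (8 with the replicate block, 7 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.000211, adjusted p = 0.632 with an estimated correlation). HSPH1 (0.90 ± 0.19), a co-chaperone of HSP70 proteins, and CHORDC1 (0.63 ± 0.13), an HSP90 co-chaperone, were among them. Of 22 genes of ATF4 and the integrated stress response, 1 rose (6 with the replicate block, 5 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.000445, adjusted p = 0.632 with an estimated correlation). That gene, PPP1R15A, encodes a phosphatase subunit that reverses the translation block and went from 307 ± 7.53 to 686 ± 109 CPM (1.16 ± 0.19). The median of the list was 0.65 in replicate 1 and 0.16 in replicate 2. Of 24 cholesterol biosynthesis genes, 4 rose (8 with the replicate block, 5 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.000457, adjusted p = 0.490 with an estimated correlation). They included the isomerase gene IDI1 (1.14 ± 0.25). MYC and ribosome biogenesis genes had a median of 0.20 over 24 genes, 0 of which were past the threshold (3 rose with the replicate block, 2 adjusted over the list alone). Camera called that list without the block (adjusted p = 0.0358, adjusted p = 0.632 with an estimated correlation) and did not with it (0.0601). Its median was 0.34 in replicate 1 and -0.05 in replicate 2, and its adjusted p was 0.759 without buffer replicate 1, 0.224 without Gal-9 replicate 1, 0.0547 without replicate 1 of Gal-9 with lactose and 0.0549 without replicate 2 of that group. The call for the stress response list ended without buffer replicate 1 (0.0877), and the heat shock and cholesterol calls were kept with each library left out.

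B cell identity genes were called as lower with Gal-9 by camera, although most of them were not past the threshold without the block. Of 16, 4 fell (8 fell and 3 rose with the replicate block, 5 fell adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0233, adjusted p = 0.632 with an estimated correlation). Beside PAX5, TNFRSF13C, the BAFF receptor gene, fell by 1.09 ± 0.24 and CD37, a tetraspanin gene, by 0.83 ± 0.14 on the log2 scale. The camera adjusted p of this list was 0.248 without Gal-9 replicate 2 and 0.156 without buffer replicate 1. KLF2 (-0.96 ± 0.15) and BACH2 (-0.91 ± 0.19), transcription factors of quiescent naive cells, fell, within a list of 16 naive and quiescent genes that was not called (camera adjusted p = 0.187). CXCR4, a homing receptor, fell from 4459 ± 397 to 2369 ± 750 CPM (-0.91 ± 0.20), and CD79A, a chain of the B cell receptor, from 2941 ± 125 to 1833 ± 181 CPM (-0.68 ± 0.13), also within uncalled lists (0.870 for adhesion and homing, 0.706 for B cell receptor signalling).

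The other lists were not called for Gal-9, and single members still passed the threshold. In the inhibitory receptor list (camera adjusted p = 0.220, median -0.04 and mean 0.32), DOK3 (1.28 ± 0.26), an adaptor that restrains receptor signalling, and CD72 (0.83 ± 0.21) rose beside FCRL4. Of its 21 genes, 3 rose and 3 fell with the replicate block, and 3 rose and 2 fell adjusted over the list alone. In the list of galectins and Gal-9 binding proteins (0.154), CD180 (1.13 ± 0.18), a toll-like receptor homologue, and LGALS1 (0.77 ± 0.17), the galectin-1 gene, rose. CD180 was also on the toll-like receptor list (0.289), where IRF5 rose by 0.56 ± 0.13. LGMN (1.49 ± 0.24) and IFI30 (1.30 ± 0.15), which encode enzymes of antigen processing, rose while HLA-DMA (-0.59 ± 0.13) fell, in the MHC class II pathway (0.968). SGK1 (1.80 ± 0.25), a kinase of salt handling, rose and WNK1 (-0.68 ± 0.14) fell in the osmotic stress list (0.727). SLAMF7 and the elongation factor gene ELL2 (1.31 ± 0.23) rose in the plasma cell list (0.726). OAS3 (1.31 ± 0.29) rose and ISG20 (-1.02 ± 0.14) fell among interferon-stimulated genes (0.739). CDKN1A (1.07 ± 0.18) rose among p53 targets (0.315). BCL2L11 (-1.02 ± 0.20) and BMF (-0.64 ± 0.14), which encode proteins that promote cell death, fell in the BCL2 family (0.189). KLHL6 rose (0.76 ± 0.16) and BCL7A fell (-0.99 ± 0.24) in the germinal centre list (0.361). ANKRD37 rose (1.03 ± 0.24) and NDRG1 fell (-0.88 ± 0.18) in glycolysis and hypoxia (0.968). HSPA5 rose (0.71 ± 0.13) among endoplasmic reticulum chaperones (0.154). ST3GAL2 fell (-0.67 ± 0.16) among glycosylation enzymes (0.930) and HIST1H4C (-1.22 ± 0.18) among histones (0.189). The regulatory B cell, cell cycle and liver X receptor lists had 0 genes past the threshold without the block (0.433, 0.399 and 0.727). With it, 3 of 14 regulatory B cell genes fell, 1 of 9 liver X receptor targets rose and 1 fell, and 0 of 16 cell cycle genes passed.

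**Figure D1:**
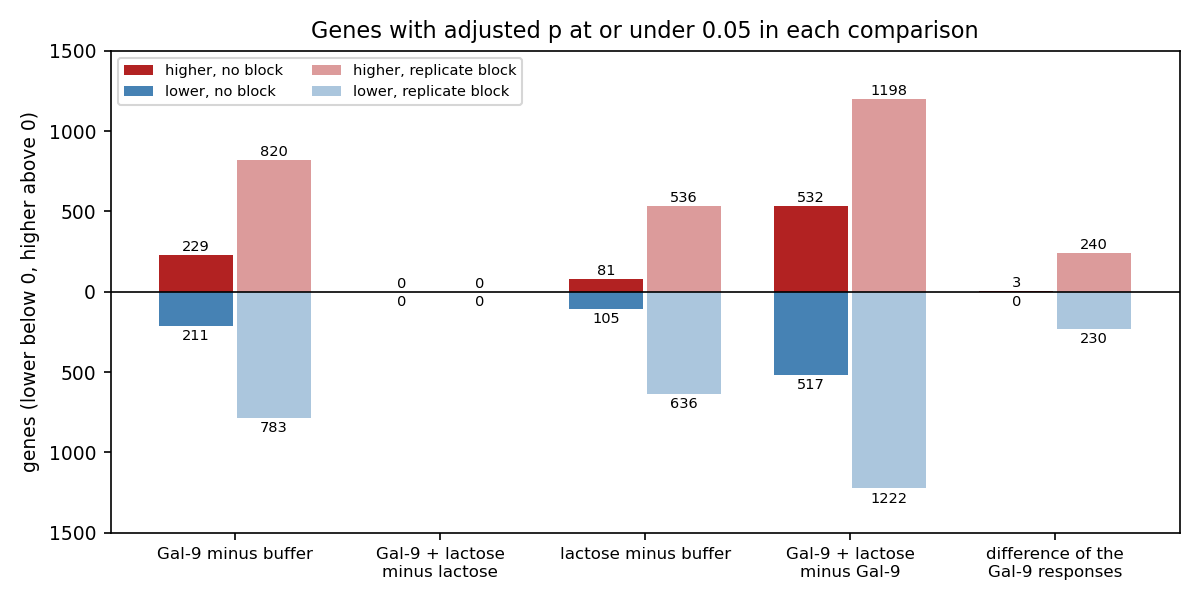
Genes with an edgeR adjusted p at or under 0.05 in each of the 5 comparisons, higher above the line and lower below it, without the replicate block (dark bars) and with it (pale bars). Gal-9 alone gave 229 genes higher and 211 lower without the block, and Gal-9 in lactose gave 0 in both fits.

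Gal-9 with lactose was compared with lactose alone to ask how much of the Gal-9 response was left when the competing sugar was present. FOS stood at 200 ± 65.2 CPM in lactose and 196 ± 69.5 CPM with Gal-9 added, CCL22 at 14.2 ± 2.57 and 22.9 ± 8.87 CPM, SLAMF7 at 103 ± 32.0 and 93.9 ± 39.6 CPM, and RPLP1 at 1609 ± 9.83 and 1692 ± 27.4 CPM. Over all genes, 0 were called by edgeR without or with the replicate block, and 0 by DESeq2 without or with it. At an unadjusted p under 0.05 there were 167 genes without the block and 356 with it, where 579 are expected by chance. limma on log2(TPM + 1) called 11 genes, on log2(TPM + 0.1) 9, and on log2(TPM + 1) without a filter 13. The genes with the smallest unadjusted p in the block fit included FAM167A, with a log2 fold change of 0.86 ± 0.22, DDX51 with 0.84 ± 0.24, UGGT1 with -0.63 ± 0.21 and KLHL8 with -0.57 ± 0.17, at an edgeR adjusted p of 1. Of 35 gene lists, camera called 0, with or without the block, and 2 without replicate 1 of Gal-9 with lactose or without lactose replicate 2. The ribosomal protein list had a median of 0.03, the lysosome list 0.02, activation markers -0.02 (mean -0.24) and immediate early genes -0.04. Changes in the 2 donors were nearly unrelated (r = 0.045 across 6236 genes).

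**Figure D2:**
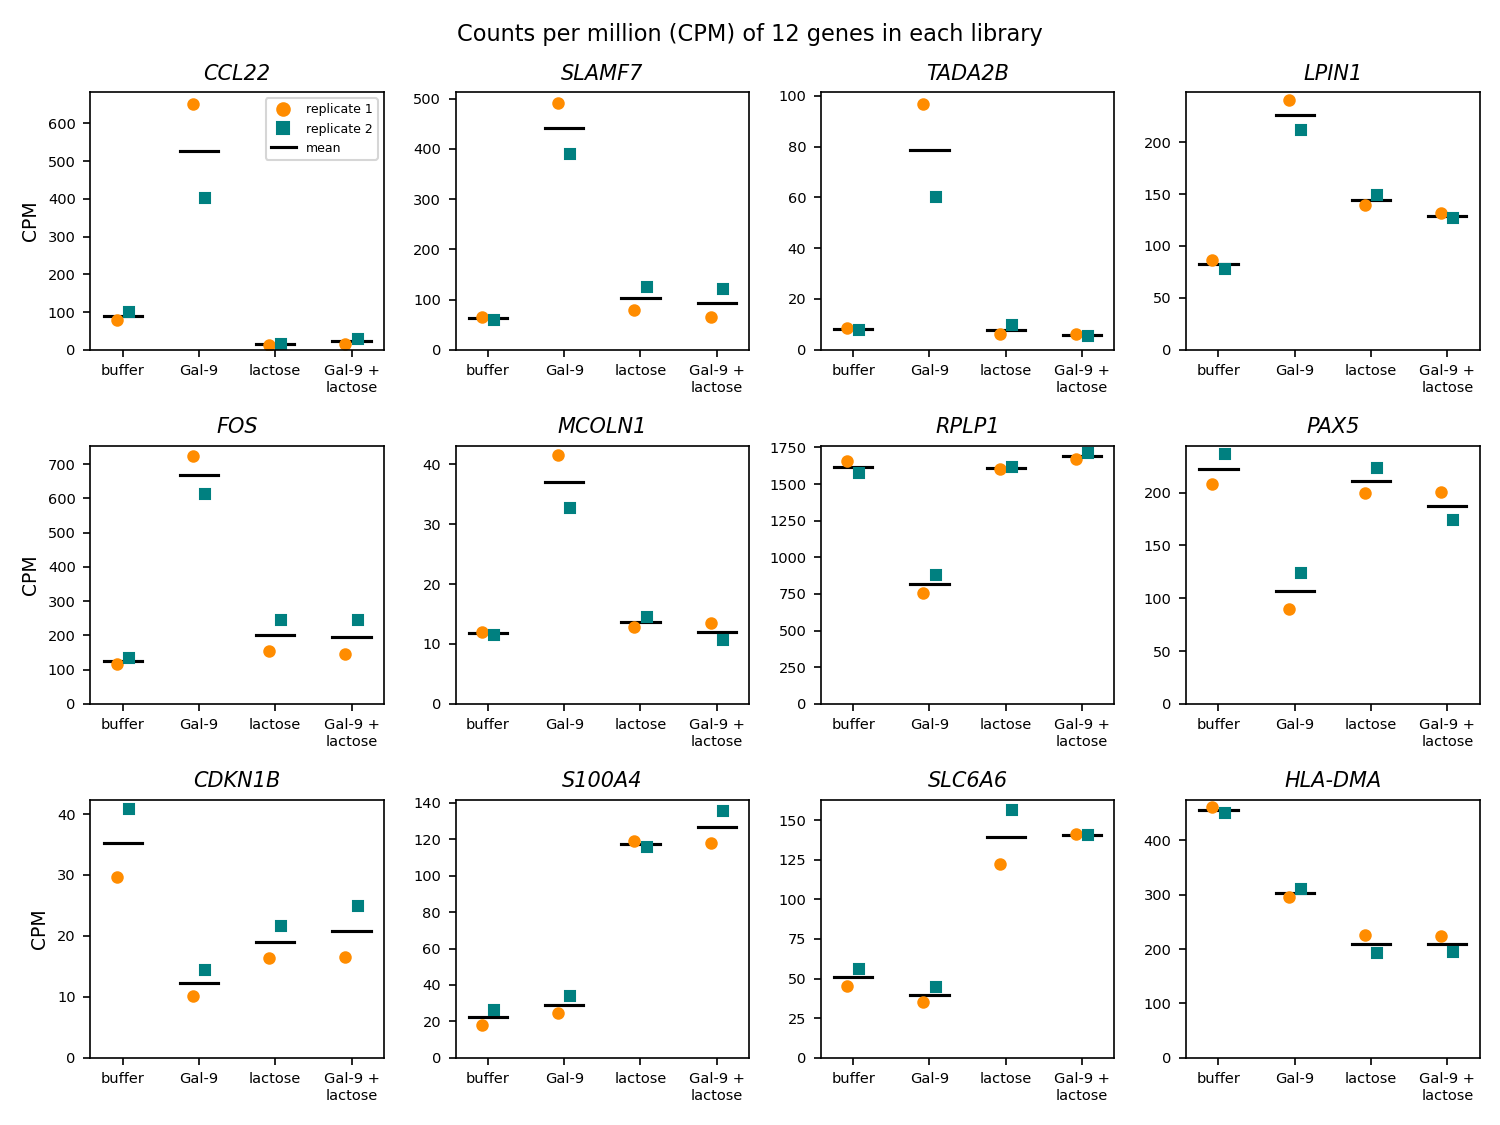
Level of 12 genes in CPM in each library, by group, with circles for replicate 1, squares for replicate 2 and a bar at the group mean. CCL22, SLAMF7, TADA2B, FOS and MCOLN1 were highest in the Gal-9 libraries, for example FOS at 668 CPM against 125 in buffer, while S100A4 and SLC6A6 were high in both groups with lactose.

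Lactose was compared with buffer to ask what the inhibitor did on its own. S100A4, which encodes a calcium-binding protein, rose from 22.1 ± 5.68 to 117 ± 2.22 CPM (2.42 ± 0.21, edgeR adjusted p = 0.0011). SLC6A6, which encodes a taurine carrier induced by hypertonic medium, rose from 50.7 ± 7.94 to 140 ± 24.2 CPM (1.46 ± 0.18, edgeR adjusted p = 0.00582). CCL22 fell from 89.8 ± 14.7 to 14.2 ± 2.57 CPM (-2.68 ± 0.32, edgeR adjusted p = 0.0143). In GRCh37, S100A4 lies on chromosome 1 from 153516089 to 153522612 and SLC6A6 on chromosome 3 from 14444076 to 14530857. In all, 81 genes rose and 105 fell, and 536 rose and 636 fell with the replicate block. The 186 genes called without the block changed the same way in both donors. Among genes with a mean log2 CPM of at least 3, the others with the largest rises were MIR22HG (2.44 ± 0.45), a long noncoding RNA, ADARB1 (2.21 ± 0.29), an RNA-editing enzyme, ANKRD50 (2.13 ± 0.41), CTNNAL1 (2.07 ± 0.26) and JDP2 (1.98 ± 0.30). Those with the largest falls were PTPRK (-2.58 ± 0.34), SIGLEC10 (-2.29 ± 0.39), BIN2 (-2.22 ± 0.26), GAA (-2.20 ± 0.39) and NEIL1 (-2.09 ± 0.37). The count was 6 without buffer replicate 1, 6 without lactose replicate 1, 32 without buffer replicate 2 and 18 without lactose replicate 2. S100A4 was the 1 gene of the 12 with the largest changes at that level that passed in each of these fits. SLC6A6 did not pass without buffer replicate 1 (adjusted p = 0.0801), and CCL22 did not without any 1 of these 4 libraries (0.0526 to 0.0916).

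Camera called 10 lists for lactose alone, and 0 of them with an estimated correlation (adjusted p of 0.644 to 0.697). The osmotic stress list was called as higher with lactose. Of 9 genes, 2 rose (4 with the replicate block, 4 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.000164, adjusted p = 0.644 with an estimated correlation). SLC38A2, an amino acid carrier gene, rose from 510 ± 57.2 to 1176 ± 15.5 CPM (1.21 ± 0.15). Of 18 heat shock genes, 3 rose (7 with the replicate block, 8 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.000656, 0.697 with an estimated correlation). They were HSPA1A (1.55 ± 0.31), which shares nearly identical sequence with HSPA1B, HSPB1 (1.34 ± 0.18) and DNAJA1 (0.73 ± 0.12). In the integrated stress response list, ATF4 itself rose by 0.71 ± 0.14 (1 of 22 genes, 4 with the replicate block, 2 adjusted over the list alone, median 0.30, camera adjusted p = 0.0115, 0.697 with an estimated correlation). Of 14 genes of the MHC class II pathway, 2 fell (6 with the replicate block, 6 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.000225, 0.697 with an estimated correlation). These were HLA-DOA (-1.41 ± 0.12) and HLA-DMA (-1.12 ± 0.13), which encode chaperones of peptide loading. Ribosomal proteins had a median of -0.27 with 0 genes past the threshold (12 fell with the replicate block, 0 adjusted over the list alone, camera adjusted p = 2.351e-08, 0.697 with an estimated correlation). Of 16 B cell identity genes 1 fell (6 with the replicate block, 3 adjusted over the list alone, median -0.27, camera adjusted p = 0.00205, 0.697 with an estimated correlation). Of 24 MYC and ribosome biogenesis genes 2 fell (5 with the replicate block, 5 adjusted over the list alone, median -0.21, camera adjusted p = 0.00282, 0.697 with an estimated correlation), ODC1 by 0.99 ± 0.17 and RRP12 by 0.72 ± 0.15. Of 23 cytokine genes 2 fell (5 with the replicate block, 4 adjusted over the list alone, median -0.36, camera adjusted p = 0.0313, 0.686 with an estimated correlation), CCL22 and LTA (-1.45 ± 0.29), which encodes lymphotoxin alpha. Of 21 inhibitory receptor genes 1, SIGLEC10, fell (7 with the replicate block, 2 adjusted over the list alone, median -0.43, camera adjusted p = 0.0408, 0.697 with an estimated correlation). Interferon-stimulated genes had a median of -0.18 (0 of 32 past the threshold, 3 fell with the replicate block, 3 adjusted over the list alone) and were called without the block (camera adjusted p = 0.0408, 0.686 with an estimated correlation) and not with it (0.0593). The osmotic, heat shock, MHC class II and ribosomal calls were kept with each library left out. Without lactose replicate 2 the adjusted p was 0.174 for B cell identity, 0.493 for the stress response, 0.135 for interferon-stimulated genes and 0.400 for inhibitory receptors. Without buffer replicate 2 it was 0.239 for MYC, 0.112 for interferon-stimulated genes, 0.185 for cytokines and 0.0621 for inhibitory receptors. Without buffer replicate 1 it was 0.419 for the stress response and 0.119 for inhibitory receptors. The cytokine call also ended without lactose replicate 1 (0.105) and Gal-9 replicate 1 (0.0738), and the inhibitory receptor call without either Gal-9 library (0.0726 and 0.0693).

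**Figure D3:**
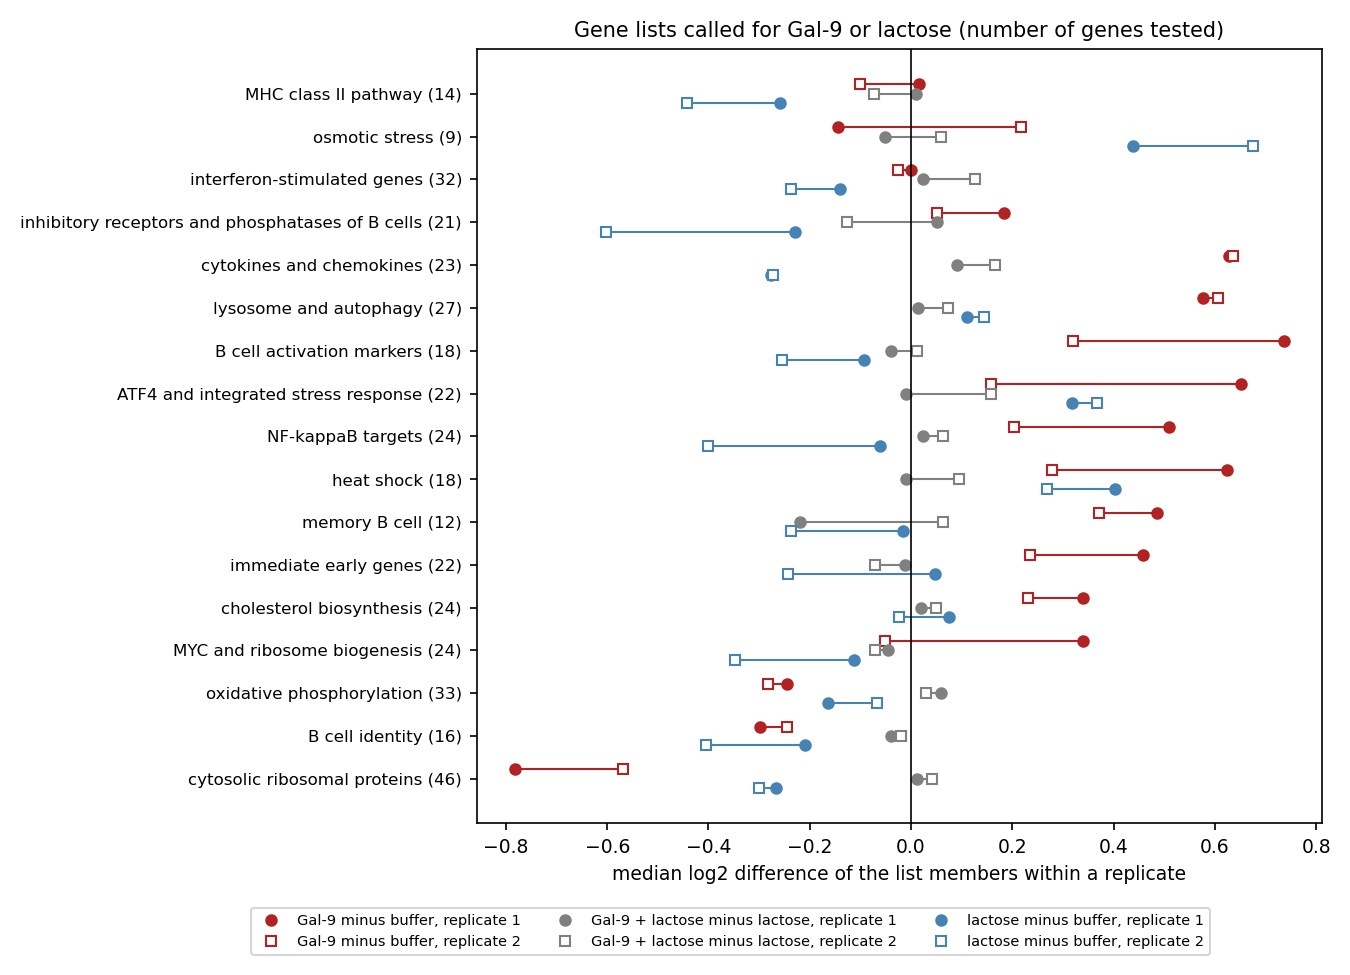
Median log2 difference of the members of each gene list within replicate 1 (filled circles) and replicate 2 (open squares), for Gal-9 minus buffer, Gal-9 plus lactose minus lactose, and lactose minus buffer. Ribosomal protein genes lay at -0.78 and -0.57 for Gal-9 in buffer and at 0.01 and 0.04 in lactose.

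Gal-9 with lactose was also compared with Gal-9 alone, to ask how adding the sugar changed cells that had received the lectin. CCL22 fell from 527 ± 176 to 22.9 ± 8.87 CPM (-4.61 ± 0.34, edgeR adjusted p = 0.00221), TADA2B from 78.5 ± 26.0 to 5.85 ± 0.78 CPM (-3.70 ± 0.34, edgeR adjusted p = 0.00221) and DOK3 from 40.7 ± 2.32 to 6.35 ± 0.74 CPM (-2.65 ± 0.30, edgeR adjusted p = 0.00239). S100A4 rose from 29.2 ± 6.72 to 127 ± 12.6 CPM (2.08 ± 0.21, edgeR adjusted p = 0.00221), and RPLP1 rose from 817 ± 89.5 to 1692 ± 27.4 CPM (1.05 ± 0.12, edgeR adjusted p = 0.00239). In all, 532 genes rose and 517 fell, and 1198 rose and 1222 fell with the replicate block. Further large rises were those of SLC5A3 (2.48 ± 0.44), a myo-inositol carrier gene, PHF19 (2.36 ± 0.38), GSG2 (2.33 ± 0.35), IKZF2 (2.24 ± 0.43) and RIMS3 (2.08 ± 0.33). Further large falls were those of CCL4 (-3.09 ± 0.50), GEM (-3.07 ± 0.50) and RNF19B (-2.70 ± 0.36). The count was 154 without replicate 1 of Gal-9 with lactose, 257 without its replicate 2 and 284 without Gal-9 replicate 1. Of the 12 genes with the largest changes among those with a mean log2 CPM of at least 3, at least 10 passed with each library left out: GEM did not without Gal-9 replicate 1, IKZF2 without either library of Gal-9 with lactose, and SLC5A3 without replicate 2 of that group.

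Camera called 15 lists for lactose in the presence of Gal-9, and 0 of them with an estimated correlation (adjusted p of 0.397 to 0.496). Of 46 ribosomal protein genes 21 rose (29 with the replicate block, 29 adjusted over the list alone, median 0.44, camera adjusted p = 5.701e-09, 0.486 with an estimated correlation). Of 24 MYC and ribosome biogenesis genes 9 fell (10 with the replicate block, 9 adjusted over the list alone, median -0.44, camera adjusted p = 4.405e-06, 0.445 with an estimated correlation), among them MYC itself (-1.10 ± 0.18). Of 18 activation markers 6 fell (10 with the replicate block, 7 adjusted over the list alone, median -0.57, camera adjusted p = 0.000252, 0.397 with an estimated correlation), with SLAMF7 at -2.26 ± 0.32. Of 24 NF-kappaB targets 9 fell (13 fell and 2 rose with the replicate block, 10 fell and 1 rose adjusted over the list alone, median -0.43, camera adjusted p = 0.00176, 0.486 with an estimated correlation). CCL3 had a log2 fold change of -3.65 ± 0.66 and TNF at -2.06 ± 0.50. Of 22 immediate early genes 6 fell (11 with the replicate block, 10 adjusted over the list alone, median -0.61, camera adjusted p = 0.00206, 0.496 with an estimated correlation), with FOS at -1.79 ± 0.29. Without Gal-9 replicate 1, edgeR's adjusted p was 0.096 for FOS and 0.0673 for SLAMF7. Of 23 cytokine genes 6 fell (7 fell and 1 rose with the replicate block, 6 fell and 1 rose adjusted over the list alone, median -1.04, camera adjusted p = 0.00429, 0.397 with an estimated correlation). Of 27 lysosome genes 7 fell (14 fell and 2 rose with the replicate block, 12 fell and 1 rose adjusted over the list alone, median -0.38, camera adjusted p = 0.00156, 0.418 with an estimated correlation). CTSA had a log2 fold change of -1.77 ± 0.20 and HEXA at -1.21 ± 0.15. Of 14 MHC class II pathway genes 5 fell (10 with the replicate block, 7 adjusted over the list alone, median -0.51, camera adjusted p = 0.000432, 0.486 with an estimated correlation). LGMN had a log2 fold change of -1.50 ± 0.25. Of 9 osmotic stress genes 5 rose and 1, SGK1 (-1.43 ± 0.26), fell, in both fits and adjusted over the list alone (median 0.52, camera adjusted p = 0.0232, 0.429 with an estimated correlation).

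Of 12 memory B cell genes 4 fell (6 fell and 1 rose with the replicate block, 5 fell and 1 rose adjusted over the list alone, median -0.67, camera adjusted p = 0.00672, 0.397 with an estimated correlation), FCRL4 by 5.31 ± 0.67 on the log2 scale. CD80, a costimulatory ligand on that list and among the activation markers, fell from 3.28 ± 0.61 CPM with Gal-9 to 0 in both libraries of Gal-9 with lactose. The medians of both lists were the same with CD80 set to its bound. Of 21 inhibitory receptor genes 4 fell and 1 rose (11 fell and 1 rose with the replicate block, 4 fell and 1 rose adjusted over the list alone, median -0.50, camera adjusted p = 0.00724, 0.496 with an estimated correlation). Of 24 cholesterol biosynthesis genes 3 fell (6 with the replicate block, 3 adjusted over the list alone, median -0.18, camera adjusted p = 0.0309, 0.496 with an estimated correlation), with IDI1 at -1.12 ± 0.25. Of 17 toll-like receptor pathway genes 2 fell (2 with the replicate block, 2 adjusted over the list alone, median -0.33, camera adjusted p = 0.0465, 0.429 with an estimated correlation), CD180 by 1.69 ± 0.19 and IRF5 by 0.99 ± 0.13. Of 11 histone genes 1, HIST1H2BK (0.76 ± 0.13), rose (4 with the replicate block, 3 adjusted over the list alone, median 0.71, camera adjusted p = 0.00335, 0.429 with an estimated correlation). Of 33 genes of oxidative phosphorylation 0 passed (4 rose and 1 fell with the replicate block, 0 adjusted over the list alone, median 0.22, camera adjusted p = 0.00724, 0.496 with an estimated correlation). With the replicate block, monocyte, macrophage and dendritic cell markers were also lower (camera adjusted p = 0.0215, 0.586 with an estimated correlation and the block, 0.0744 without the block), with 5 of 10 genes fallen in that fit and a median of -3.79, or -3.58 with members at 0 in a group set to their bound. Their median was 0 in replicate 1 and -3.50 in replicate 2, and without Gal-9 replicate 2 the list was not called (0.979, without the block). Among the lists too short for camera, 2 of 4 plasmacytoid dendritic cell markers and 1 of 4 follicular dendritic and stromal markers fell. Without Gal-9 replicate 2 the adjusted p was 0.0711 for cholesterol biosynthesis, 0.0579 for osmotic stress and 0.197 for the toll-like receptor pathway. Without replicate 1 of Gal-9 with lactose it was 0.113, 0.0583 and 0.113 for these and 0.0956 for memory genes. Without replicate 2 of that group it was 0.0777 for toll-like receptors, 0.101 for inhibitory receptors and 0.0881 for oxidative phosphorylation.

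A test of the difference between the Gal-9 responses without and with lactose asked whether the sugar changed the response. LPIN1, which encodes a phosphatidate phosphatase, went from 82.2 ± 5.51 to 226 ± 19.8 CPM with Gal-9 and from 144 ± 6.84 to 129 ± 3.50 CPM with Gal-9 in lactose, a difference in log2 response of 1.62 ± 0.18 (edgeR adjusted p = 0.028). TADA2B (3.63 ± 0.47, edgeR adjusted p = 0.0371) and PLXNA1 (3.52 ± 0.46, edgeR adjusted p = 0.0371) were the other genes that passed. LPIN1 stayed past the threshold only without either Gal-9 library, with an adjusted p of 0.0643 to 0.139 without any other 1 library, and TADA2B and PLXNA1 only without Gal-9 replicate 2 (0.0717 to 0.190 and 0.0805 to 0.176 otherwise). With the replicate block 470 genes passed, 240 of them with a more positive and 230 with a more negative response without lactose. RNF19B (3.23 ± 0.50), BRD1 (3.01 ± 0.56), SLAMF7 (2.97 ± 0.44), SDK2 (-2.92 ± 0.52), HIST1H1D (-1.91 ± 0.77), MGAT5B (-1.82 ± 0.35), LIMK1 (-1.63 ± 0.30) and CDKN1B (-1.59 ± 0.43) were among those past the threshold with the block only. The count without the block was 215 without Gal-9 replicate 2, and 0 without buffer replicate 2 or without any 1 of the 4 libraries that held lactose. In those 5 cases edgeR's count is 0 against 1363 genes at an unadjusted p under 0.05 with all libraries, and DESeq2 called 163 genes with all libraries.

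Camera called 11 lists for the difference of the responses, and 0 of them with an estimated correlation (adjusted p of 0.548 to 0.730). The ribosomal protein response differed by a median of -0.71 (camera adjusted p = 5.249e-23, adjusted p = 0.548 with an estimated correlation), with 34 of 46 genes past the threshold with the replicate block, 0 without it and 39 adjusted over the list alone. The lysosome response differed by 0.56 (camera adjusted p = 1.499e-05, adjusted p = 0.548 with an estimated correlation), with 10 of 27 genes past the threshold with the block, 0 without it and 11 adjusted over the list alone. The oxidative phosphorylation response differed by -0.34 (camera adjusted p = 0.000314, 0.571 with an estimated correlation), with 0 genes past the threshold in either fit. These 3 calls were kept with each library left out. The other called lists had medians of 0.59 for activation markers (camera adjusted p = 0.00511, 0.548 with an estimated correlation), 0.42 for immediate early genes (0.00894 and 0.599), 0.36 for heat shock (0.00894 and 0.599), 0.30 for MYC and ribosome biogenesis (0.0152 and 0.599), 0.44 for the integrated stress response (0.0154 and 0.730), 0.25 for NF-kappaB targets (0.0166 and 0.592), 0.18 for cholesterol biosynthesis (0.0243 and 0.592) and 0.38 for memory genes (0.0248 and 0.548). Of their members 0 were past the threshold without the block, and with it a larger Gal-9 response without lactose passed for 5 activation markers, 5 immediate early genes, 3 NF-kappaB targets, 3 heat shock genes, 2 cholesterol biosynthesis genes and 1 gene each of the MYC, stress response and memory lists. Adjusted over the list alone, 3 activation markers, 3 immediate early genes and 1 memory gene passed. Without Gal-9 replicate 2 the camera adjusted p was 0.0787 for activation markers, 0.127 for immediate early genes, 0.0867 for NF-kappaB targets, 0.0831 for memory genes and 0.0787 for both the integrated stress response and cholesterol biosynthesis. Without buffer replicate 1 it was 0.0891 for activation markers and heat shock, 0.352 for NF-kappaB targets, 0.272 for the stress response and 0.257 for immediate early genes, MYC and cholesterol biosynthesis. Without replicate 1 of Gal-9 with lactose it was 0.0942 for immediate early genes and heat shock, 0.0877 for NF-kappaB targets and MYC, 0.253 for memory genes, 0.590 for the stress response and 0.0974 for cholesterol biosynthesis. The calls for MYC (0.0701) and heat shock (0.0717) also ended without Gal-9 replicate 1, and those for immediate early genes (0.117), NF-kappaB targets (0.0624), the stress response (0.38) and cholesterol biosynthesis (0.0944) without lactose replicate 2. With the replicate block camera also called p53 targets (0.0418, 0.0765 without) and T cell markers (0.0375, 0.393 without), and neither with an estimated correlation and the block (0.482 and 0.660). The T cell marker median was 0 in replicate 1 and 1.34 in replicate 2, and the list was not called without Gal-9 replicate 2 (0.569, without the block).

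Across 11581 genes the Gal-9 changes without and with lactose, which share no library, correlated with r = 0.016 (Spearman rho = -0.007; r = -0.003 and 0.032 within the donors), and r ranged from -0.208 without replicate 2 of Gal-9 with lactose to 0.183 without lactose replicate 2. The lactose changes without and with Gal-9, which also share no library, correlated with r = 0.446 (rho = 0.411; r = 0.316 and 0.403 within the donors). That value was 0.160 without buffer replicate 2, 0.270 without lactose replicate 1 and at least 0.317 without any other 1 library. It was 0.152 with no filter on low counts, 0.476 with a stricter one and 0.590 over the genes called in either comparison with the replicate block. Over such genes the correlation of the Gal-9 changes was 0.129.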

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

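The test of marker genes against IL1B, IL32, CXCL8 and CCL5, the folds of summed markers, and the fit with length and GC trends removed, were chosen after the results were seen.

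Each result here stands out because the Gal-9 response without lactose differed, by a test of the difference itself, from the response with lactose. The values below come from fits without the replicate block. With the block, 470 genes passed the test of the difference. The difference in log2 response was 1.62 for LPIN1 (1.46 without and -0.16 with lactose), 3.52 for PLXNA1 (2.85 and -0.68) and 3.63 for TADA2B (3.25 and -0.38), at edgeR adjusted p of 0.028, 0.0371 and 0.0371. Of the lists, cytosolic ribosomal proteins differed by a median of -0.71 (-0.67 without and 0.03 with lactose, camera adjusted p = 5.249e-23), oxidative phosphorylation by -0.34 (-0.29 and 0.04, 0.000314) and lysosome and autophagy by 0.56 (0.64 and 0.02, 1.499e-05). B cell activation markers differed by 0.59 (0.61 and -0.02, 0.00511), immediate early genes by 0.42 (0.34 and -0.04, 0.00894), heat shock by 0.36 (0.39 and 0.03, 0.00894) and MYC and ribosome biogenesis by 0.30 (0.20 and -0.08, 0.0152). ATF4 and the integrated stress response differed by 0.44 (0.45 and 0.07, 0.0154), NF-kappaB targets by 0.25 (0.39 and 0.04, 0.0166), cholesterol biosynthesis by 0.18 (0.26 and 0.04, 0.0243) and memory B cell genes by 0.38 (0.37 and 0.00, 0.0248). With an estimated correlation 0 of these lists were called. With single libraries left out, the 3 genes and the lists other than ribosomal proteins, oxidative phosphorylation and lysosome each lost their call at least once.

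The first pattern weighed was the lower level of ribosomal protein transcripts with Gal-9 than with buffer. Ribosomal protein genes are short, so a length bias could lower them all. In 230 genes outside the list, matched on length and level, the median log2 fold change was -0.19 (bootstrap interval -0.24 to -0.13 from 1000 resamples), against -0.67 in the list and a bound of -0.33 for a bias that explains at least 50% of it. The match was incomplete, with a median length of 1075.5 bp against 788.5 bp. For 230 genes matched on GC content and level the median was -0.052 (-0.097 to -0.007). With smooth length and GC trends removed from each library and the replicate block, 39 of 46 ribosomal protein genes were lower, and their median was -0.62 against -0.68 before. These values argue against length or GC content as the whole source, and a smaller part from length stays open. Gal-9 itself, which the design names, is a candidate explanation and was not tested apart from the groups.

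The second pattern was the higher level of activation markers, NF-kappaB targets and cytokine genes with Gal-9. RNA of other cells in the Gal-9 libraries could raise such genes, since markers of other cells were still counted after the bead sort for naive B cells. In replicate 2, CPM in buffer and Gal-9 were 3.27 and 21.3 for LYZ, 7.69 and 27.0 for CD14, 2.5 and 17.6 for S100A9, 8.27 and 40.9 for CD68, and 3.27 and 11.5 for CD2. Summed over 24 monocyte, macrophage and dendritic cell markers, the rise was 235 CPM in replicate 2, which is 6.73% of the rise of 3487 CPM in the 26 pattern members called with the block, and -0.02% in replicate 1, where the members rose by 5102 CPM. For 19 T cell markers it was 2.18% and 0.07%. Before the results were seen, a share under 10% in both replicates had been set to speak against RNA of such cells, and both lists met it. How large these shares would be in RNA of such cells is not known, so that bound was set aside and the shares decide nothing. Cells that hold at least as many marker counts per member count as the buffer library would raise the markers at least as much as the members, which rose 1.69-fold in replicate 1 and 1.41-fold in replicate 2. In replicate 1 the fold was 0.986 for the monocyte, macrophage and dendritic cell markers (counting interval 0.813 to 1.19) and 1.07 for T cell markers (0.87 to 1.30). The summed markers thus did not rise with the members in replicate 1. The counting interval holds no variation between libraries, and the members were picked because they rose in these data. A fall of the markers in the B cells themselves could also hide a rise. The folds therefore do not settle whether these cells were a source of the rise there. S100A9, FCER1G and CST3 were at 0 CPM in buffer and Gal-9 of replicate 1. LYZ, CD14, S100A8 and TYROBP lay at 0.13 to 0.52 CPM in that buffer library and at 0 in Gal-9. The monocyte, macrophage and dendritic cell sums there thus came mostly from CD68 (14.08 and 10.99 CPM) and other list members. CD3D, CD3E, CD2 and CD4 were at 0 CPM in buffer and Gal-9 of replicate 1, so the T cell sums came from other list members. In replicate 2, at 4.74 and 2.85, a contribution of these cells cannot be told apart from a response of the B cells. RNA of plasmacytoid dendritic cells stays open in both replicates, with folds of 2.13 (1.80 to 2.53) and 1.45 (1.25 to 1.70) over 8 markers, of which PLD4 held 74.5 of 94.1 CPM in Gal-9 replicate 1. LILRA4, another of them, rose from 3.78 to 16.7 CPM in replicate 1 and from 0.77 to 5.91 CPM in replicate 2. It lay at 0 to 1.06 CPM in the libraries with lactose. All 4 tested markers of this list had a log2 fold change above 0. For IL1B, IL32, CXCL8 and CCL5, whose log2 differences were 3.29, 3.25, 2.76 and 2.40 in replicate 2 and at most 0.86 in replicate 1, the case differs. The monocyte, macrophage and dendritic cell markers had a median log2 difference of 2.23 in replicate 2 and -0.39 in replicate 1 (10 tested markers). For T cell markers the medians were 1.69 and 0 (11 tested), and for NK cell markers 2.19 and 0 (3 tested). In buffer and Gal-9 of replicate 1, CD3D, CD3E, CD2, NKG7 and GNLY were at 0 CPM, so the medians of 0 there reflect a lack of detection. RNA of any of these cell types in Gal-9 replicate 2 may therefore account for IL1B, IL32, CXCL8 and CCL5, and these values cannot tell which type. The response of B cells to Gal-9 stays a candidate explanation for the other members, as a hypothesis found on these data.

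The third pattern was that edgeR called 0 genes for Gal-9 when lactose was present (167 at an unadjusted p under 0.05, 0 by DESeq2, 9 to 13 by limma on TPM), against 440 without it. Lower depth could hide a response. With the libraries without lactose thinned to the depth of their lactose partners where deeper, 450 to 482 genes were still called over 5 draws. Gal-9 replicate 1, at 2487191 counts, was already shallower than its partner at 4244487 and was not thinned. A wider spread between replicates could do the same. The median replicate difference in the groups with lactose, over that in the others and with the donor mean removed, was 0.898 (0.883 to 0.922 over 6236 genes). That interval came from resampled genes, which are not independent replicates. The mean removed was taken over all 4 groups, which ties the parts of the ratio together. The thinned counts argue against lower depth. The ratio showed no wider spread with lactose, but it cannot decide the count, since edgeR shared its spread estimate over all 8 libraries. Competition of lactose for the Gal-9 binding sites is the explanation the design names, and it stays a hypothesis, since an effect of lactose on the cells that blunts the response by another route was not tested.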

How the results depend on the processing

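The fit with length and GC trends removed, and camera with an estimated correlation and the block, were chosen after the data were seen. Counts below are in the order Gal-9 without lactose, lactose without Gal-9, lactose with Gal-9 and difference of the Gal-9 responses, against 440, 186, 1049 and 3. The 0 genes for Gal-9 with lactose stayed 0 by edgeR and DESeq2 under each alternative, while 167 had an unadjusted p under 0.05.

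The replicate block gave 1603, 1172, 2420 and 470 genes, among them all those called without it (440, 186, 1049 and 3). The common coefficient of variation was 0.107 in that fit and 0.171 without the donor term. The replicate block with RLE size factors gave 1621, 1164, 2421 and 462. DESeq2 gave 685, 340, 1083 and 163, of which 418, 184, 932 and 1 were shared with edgeR, and DESeq2 with the replicate block gave 1129, 700, 1708 and 430. Without a low-count filter edgeR gave 1265, 793, 1885 and 402. With length and GC trends removed and the replicate block the counts were 1465, 1184, 2295 and 350. Of the 1465 for Gal-9 without lactose, 1210 were among the 1603 called with the block alone. Across genes, Spearman rho of the log2 fold change with GC content was -0.254 for Gal-9 without lactose and 0.21 with it. It was -0.09 for lactose without Gal-9, 0.223 with Gal-9 and -0.311 for the difference of the responses. Only the 2 groups compared gave 244, 189 and 562, with fewer libraries to estimate the spread. The cause of these differences in count was not tested. RLE alone (445, 182, 1046 and 3), the stricter filter and leaving out immunoglobulin genes stayed within 1.5 times.

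Limma on log2(TPM + 1) called 245 (163 higher, 82 lower), 77 (45 higher, 32 lower), 889 and 14, and 11 for Gal-9 with lactose. On log2(TPM + 0.1) it called 236 (156 higher, 80 lower), 66 (40 higher, 26 lower), 869 and 1, and 9 for Gal-9 with lactose. Without a filter log2(TPM + 1) gave 39 (25 higher, 14 lower), 39 (20 higher, 19 lower), 397 (147 higher, 250 lower) and 8, and 13 for Gal-9 with lactose. The cause was not tested.

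Leaving out 1 library assumes that the lone library left in its group varies like the other groups. Without a donor term, that group then holds 1 donor while the others hold both, so differences between the donors enter the comparison. The counts ranged from 6 (without buffer replicate 1) to 893 (without Gal-9 replicate 2) for Gal-9 without lactose, of which 370 were shared, from 6 (without buffer replicate 1 or lactose replicate 1) to 253 for lactose without Gal-9, from 154 (without replicate 1 of Gal-9 with lactose) to 1274 (without Gal-9 replicate 2) for lactose with Gal-9, and from 0 to 215 (without Gal-9 replicate 2) for the difference. For Gal-9 with lactose the range was 0 to 0. With the replicate block they ranged from 423 to 2439, 243 to 2200, 805 to 2850 and 61 to 1635, and stayed 0 for Gal-9 with lactose. Leaving out a whole donor leaves no residual degrees of freedom. With fewer libraries in a group the test loses power, and the cause of the rise without Gal-9 replicate 2 was not tested.

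Of 13, 10, 15 and 11 lists called, 0 were called with an estimated correlation, with or without the replicate block, and fry called 2, 1, 11 and 0. Camera with an estimated correlation also missed the simulated lysosome list that was shifted 1.5-fold (adjusted p = 0.103). Its 0 calls therefore do not show that no list moved. Camera with the replicate block called 13, 9, 16 and 13, and without a filter 15, 10, 18 and 12. With each library left out the counts ranged from 7 to 15, 6 to 13, 12 to 19 and 4 to 15, and from 0 to 2 for Gal-9 with lactose.

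The correlation of the Gal-9 changes without and with lactose (0.016) was 0.129 over the 1603 genes called in either comparison with the replicate block, and ranged from -0.208 (without replicate 2 of Gal-9 with lactose) to 0.183 (without lactose replicate 2). That of the lactose changes (0.446) was 0.590 over 3034 called genes with the replicate block and 0.152 without a filter, and ranged from 0.160 (without buffer replicate 2) to 0.461; the cause was not tested.

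Of the named gene results under all alternatives, 6944 were the same, 1236 crossed to past the threshold, 804 fell short of it and 4 reversed; of the list results 484 were the same and 202 fell short. The change of CXCL8 in Gal-9 without lactose reversed on log2(TPM + 0.1), to -0.42 ± 4.43, and without Gal-9 replicate 2, to -7.85 ± 8.96. Its range was -7.85 to 5.58 over the libraries left out. Without Gal-9 replicate 2, the change of CCL5 in Gal-9 without lactose reversed to -2.53 ± 4.04 (range -2.53 to 6.63). That of CCL5 in lactose with Gal-9 reversed to 1.85 ± 4.34 (range -10.19 to 1.85). Each of these reversed values was smaller than its SE. For these, the high values lay in the library left out. The fits had no donor term, so they set Gal-9 of replicate 1 against buffer of both donors. Within replicate 1 the log2 difference between Gal-9 and buffer was 0.86 for CCL5 and -1.66 for CXCL8, so CCL5 was not lower with Gal-9 in that donor. Among the calls in the report, the replicate block ended those of the MYC list for Gal-9 without lactose and interferon-stimulated genes for lactose without Gal-9, and it ended no gene call of the report. At these depths 41.8% of simulated 2-fold changes were recovered without the block.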

Other observations

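The tests given here were written before their results were seen.

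Because lactose alone changed 186 genes, it was asked whether lactose moves genes in the direction opposite to Gal-9. The Gal-9 change in one donor was correlated with the lactose change in the other donor, since these share no library. Across 6236 genes, which are not independent replicates, r was 0.223 and 0.227 in the 2 pairings, where a value below -0.1 was needed for opposite changes. Within a donor, where both changes share the buffer library, r was 0.340 and 0.315. The values argue against opposite changes across the transcriptome, and single genes, such as CCL22, moved in opposite directions. They say nothing on why 0 genes were called for Gal-9 in the presence of lactose, since an opposite lactose effect that adds to that of Gal-9 cancels in that comparison. Changes in the same direction could leave less room for a Gal-9 response, which was not tested.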
